A study of Mus musculus with 12 samples.

How the data were processed

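Messenger RNA of sorted mouse hepatocytes was measured in 12 libraries with the Ion AmpliSeq mouse transcriptome panel, which reads 1 amplicon per gene, on an Ion S5 sequencer. Per the labels, RNA was isolated with the RNAqueous Micro kit from cells sorted for GFP or TdTomato and against Epcam and CD45. The values deposited by the authors are log2 CPM, the log2 of reads scaled to a common library total, for 16116 gene symbols, and the labels call the same scale RPM. The aligner, the counting tool, the genome build and any later adjustment are not given in the sources used here.

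The structure of the deposited table was checked before any comparison. Gene by gene, the means of the 2 GFP control groups were equal to within a median of 0.00849, with 98.9% of the kept genes within 0.05. In the Mst experiment the means of the first and of the second libraries were equal too (median difference 0.0051, 99.9% within 0.05), which was not so in the YAP experiment (0.168, 15.6%). The centred table had 9 singular values over 10, the ninth at 34.5 and the next at 1.88. Differences among the 4 activated group means lay on a grid of 0.005. Those from the mean of all 4 control libraries lay on a grid of 0.0025, while 26.8% of the differences between the Sox9-heterozygous YAP group and the control mean of its experiment lay on the grid of 0.005. The deviations of libraries from their group mean were whole multiples of 1 step per gene in 16078 of 16080 genes, to a tolerance of 2e-06. Of 1000 random sets of deviations, 0 met this with multiples as small. The deviations had therefore been multiplied by 1 factor per gene, with a median of 1.57 (5th and 95th percentiles 0.964 and 2.96), and the median SD within groups was 0.289 as deposited and 0.188 before that rescaling. Comparisons within an experiment are unchanged if the step that made the controls equal moved all libraries of an experiment alike, which the values do not show, and the comparison of the controls is void. The steps also bear on every p-value. Whole reads could not be recovered, so an alternative chosen before the data were examined, limma-voom on reads, was not run. The linear values summed to 879620 to 1011693 per library, and the 10 largest genes held 13.4% to 16.4% of the sum. Replicates correlated with r of 0.953 to 0.982 across genes, which are not independent replicates.

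Groups were taken from the labels, 2 libraries in each of 6 groups. Genes with log2 of at least 1 in at least 2 libraries were kept, 10681 in all. Group means were fitted to the deposited values over all 12 libraries with limma 3.58.1 in R 4.3.3, with a trended prior variance. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The comparisons were each YAP-activated group against the GFP control of its experiment, Sox9-null against Sox9-heterozygous in each experiment, the GFP controls with each other, and the differences between experiments of the activation effects (Sox9-heterozygous groups) and of the Sox9 loss effects. Sox9 loss was also fitted over the 8 libraries of both experiments with the experiment as a term. Genes called in both experiments were counted against the number that independent lists would share. Genes called for activation in one experiment were tested under Sox9 loss in the other with camera. Comparisons that share control libraries were not set against each other.

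Of 31 gene lists fixed before the data were examined, 27 had at least 5 kept genes and were tested in 6 comparisons with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The lists were YAP and TAZ targets, Hippo components, cholangiocyte and progenitor markers, Notch, TGF-beta, extracellular matrix, hepatocyte transcription factors and secreted proteins, pericentral, periportal, bile acid, drug metabolism, cholesterol and fatty acid synthesis, fatty acid oxidation, glycolysis, cell cycle, p53 and apoptosis, fetal liver and liver tumour markers, chemokines and cytokines, interferon, acute phase, immediate early genes, actin and integrins, male-biased and female-biased liver genes, and markers of macrophages, endothelial cells, stellate cells, T and NK cells, B cells, neutrophils and erythroid cells. Of 91 calls, 3 held with a correlation estimated from the residuals: the cholangiocyte and progenitor markers in both Sox9-heterozygous groups, and the pericentral genes in the Sox9-heterozygous Mst group. The self-contained test fry called 46.

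The genes named follow a rule set before the data were examined. Sox9, Stk4, Stk3, Yap1, Xist and 4 Y-linked genes were always taken. For each comparison of 2 groups within an experiment and for Sox9 loss over both experiments, up to 12 genes with the largest rise and up to 12 with the largest fall were taken among those with an adjusted p under 0.05, no overlap between libraries and a mean log2 of at least 4 in the higher group. Up to 5 in each direction were taken for the differences between experiments, and up to 4 members per list that passed, or else up to 2 given as values alone. Positions are from GENCODE M21 on GRCm38, where 10436 of the kept symbols were found. The 23 symbols stored as dates were left as they were.

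The test was checked on simulated data of the same size. Of 200 changed genes 135 were called, with 2 unchanged genes called and 0 of the wrong sign. The share called was 22.4% at a log2 change of 1, 85.1% at 2 and 95.5% at 3. With no change, 5.00% of genes had p under 0.05 for independent libraries. With the Mst libraries made equal as in the deposited values the share was 7.41%, and it was 4.97% with the library number in the model. These shares are for the Sox9-heterozygous Mst comparison, the only one simulated this way, and by that step alone its p-values run somewhat low. All 6 groups share 1 estimate of the spread, so the step bears on the YAP comparisons too. The rescaling of the deviations, which enlarged the median SD, was not simulated, so the net direction is not known. The list test called a list of 20 genes raised by log2 1 in 20 of 20 tables and 3 of 380 unchanged lists. Genes were drawn independently here, so this check does not cover lists whose members move together. In the data the estimated correlation within a list ran from -0.05 (glycolysis) to 0.69 (male-biased genes).

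The alternatives fixed before the data were examined were no filter, a filter at log2 3, fits within an experiment, equal library medians, quantile normalization, an untrended prior variance, 10 added on the linear scale, the replicate number as a block, and each library left out in turn, where a lone library is assumed to vary like the other groups. Those chosen after seeing the data were the library number of the Mst experiment as a term, deviations divided by the rescaling factor, both together, an estimated correlation and sets without endothelial markers in the test of Sox9 dependence, and leaving out libraries in the agreement of the experiments. Structure and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.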

Results

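The series measured messenger RNA in mouse hepatocytes in which the transcriptional coactivator YAP had been activated in 2 ways, with the transcription factor gene Sox9 deleted from 1 or from both alleles. Its title gives the purpose as the role of Sox9 in such cells. There were 12 libraries in 6 groups of 2. In the YAP experiment, wild type mice received an adeno-associated virus that makes green fluorescent protein (GFP) from the hepatocyte promoter TBG. Mice with 1 or 2 floxed Sox9 alleles received virus for Cre recombinase and for YAP S127A, a mutant that escapes inhibitory phosphorylation by the Hippo pathway. These groups are called the wild type control, the Sox9-heterozygous YAP group and the Sox9-null YAP group. In the Mst experiment, mice carried floxed Mst1 and Mst2, the Hippo kinase genes (symbols Stk4 and Stk3) whose loss leaves endogenous YAP active. They received GFP virus, or Cre virus together with 1 or 2 floxed Sox9 alleles, and the groups are called the floxed control, the Sox9-heterozygous Mst group and the Sox9-null Mst group. Mice were injected at 3 weeks of age, and fluorescent hepatocytes negative for the biliary marker Epcam and the leukocyte marker CD45 were sorted 3 weeks (YAP experiment) or 4 weeks (Mst experiment) later. Control mice received no Cre, so each comparison with a control holds the effects of Cre, of the Sox9 deletion and of YAP activation together. Cells were sorted for GFP or TdTomato. Which of these was used for each group is not given here, so any difference in the gate would be held in these comparisons too. The means of the 2 controls had been made equal gene by gene before deposition, and the values do not show whether the other libraries of an experiment were moved alike. Read depth is not given in the sources used here. Summed over genes, the linear values came to between 879620 and 1011693 per library, and 9919 to 10392 genes reached log2 1 in each library. The 4 GFP control libraries had the lowest sums, 879620 to 920020, against at least 938683 in the others. They also had the fewest genes at log2 1, 9919 to 10005, against at least 10118. The scale of the libraries therefore went with activation. The labels do not say that the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. The deviations of the 2 libraries from their group mean had also been rescaled gene by gene before deposition, and all tests use them as deposited. With the deviations before that rescaling, a setting chosen only after the result was seen, the counts of the 6 comparisons below were 1232, 2955, 499, 2115, 2795 and 205 in place of 168, 760, 18, 454, 829 and 5. In the text, ± after a change is the SE, and ± after a level is the SD of 2 libraries.

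The targeted genes were examined first. Sox9, a marker of bile duct and progenitor cells in liver, lies on chromosome 11, 112782224 to 112787760, plus strand (GRCm38, GENCODE M21). Its level was 3.74 ± 0.22 log2 CPM (reads scaled to a common library total) in the wild type control, 4.84 ± 0.62 in the Sox9-heterozygous YAP group and 2.45 ± 0.24 in the Sox9-null YAP group. In the Mst experiment it was 3.73 ± 0.85 in the floxed control, 6.23 ± 0.33 in the Sox9-heterozygous group and 1.35 ± 0.09 in the Sox9-null group. Between Sox9-null and Sox9-heterozygous hepatocytes Sox9 fell by 2.40 (log2, SE 0.38, adjusted p = 0.0132) under YAP S127A and by 4.88 (SE 0.38, adjusted p = 6.31e-06) after Mst deletion. Against the controls Sox9 rose in the Sox9-heterozygous Mst group (2.50 ± 0.38, adjusted p = 8.15e-04) and fell in the Sox9-null Mst group (-2.38 ± 0.38, adjusted p = 8.73e-04). The values in the YAP experiment did not pass (1.10 ± 0.38, adjusted p = 0.225 and -1.29 ± 0.38, adjusted p = 0.0519). Yap1 (chromosome 9, 7931999 to 8004596, minus strand) rose in the Sox9-null YAP group (1.19 ± 0.24, adjusted p = 0.00556). Its log2 difference from the control was 0.91 ± 0.24, adjusted p = 0.0755 in the Sox9-heterozygous YAP group, and -0.16 and 0.15 in the Mst groups. The floxed kinase genes did not pass in either Mst group. Stk4 (chromosome 2, 164070322 to 164155524) differed from the control by -0.36 ± 0.25, adjusted p = 0.547 and -0.56 ± 0.25, adjusted p = 0.222. For Stk3 (chromosome 15, 34875496 to 35178921) the differences were 0.22 ± 0.27 and 0.31 ± 0.27 (adjusted p = 0.779 and 0.621). The assay reads 1 amplicon per gene whose place in the gene is not given in the sources used here, so an amplicon outside the floxed exons would not show the deletion. The Sox9 call under YAP S127A ended without library 2 of the Sox9-heterozygous YAP group (-1.96) and without library 1 (-2.22) or library 2 (-2.57) of the Sox9-null YAP group. The Yap1 call ended without library 2 of the wild type control (1.10) or library 2 of the Sox9-null YAP group (0.91). All 12 libraries carried Y-linked transcripts, with Ddx3y between 4.46 and 5.76, and had Xist between 0.99 and 1.52.

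**Figure D1:**
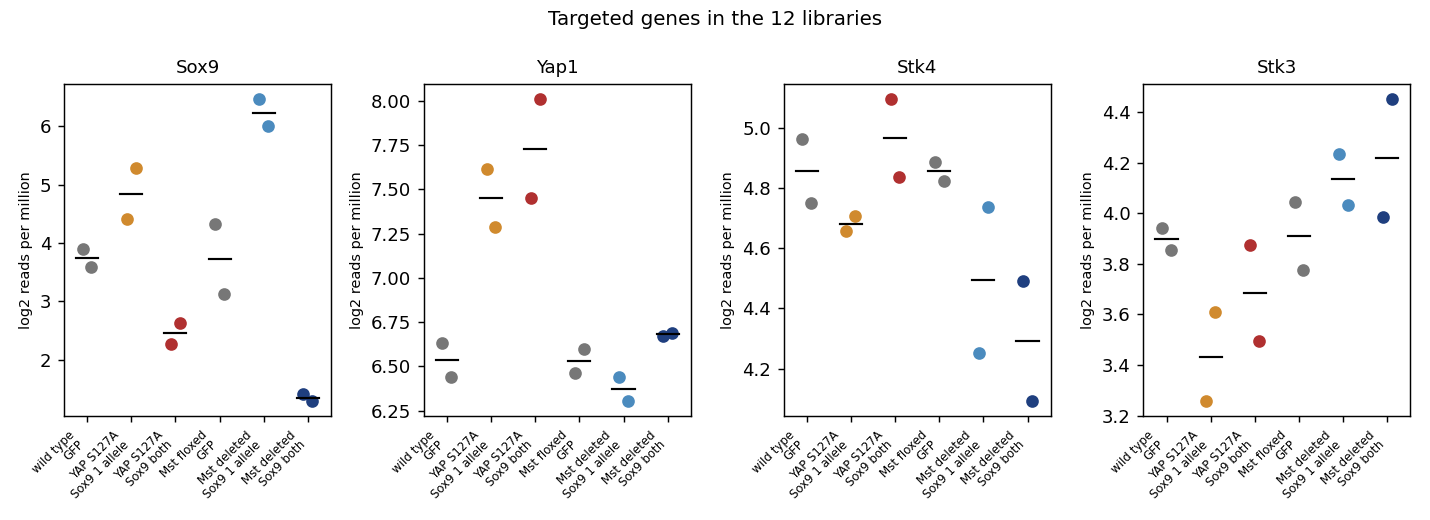
Levels of Sox9, Yap1, Stk4 and Stk3 (log2 CPM) in the 12 libraries, 1 point per library, with a bar at the mean of the 2 libraries of each group. Sox9 means were 1.35 in the Sox9-null Mst group and 6.23 in the Sox9-heterozygous Mst group, and the Yap1 mean was 7.73 in the Sox9-null YAP group.

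The first comparison asked what YAP S127A with 1 Sox9 allele deleted did against the wild type control. In this and the following comparisons, largest changes are named among called genes with a mean log2 of at least 4 in the higher group and no overlap between libraries. The largest rise among the named genes was that of Gpc3, a cell surface proteoglycan of fetal liver and liver tumours (5.91 ± 0.46, adjusted p = 6.37e-06). The direct YAP target Ctgf (4.49 ± 0.35, adjusted p = 6.37e-06) and the progenitor transcription factor Sox4 (4.16 ± 0.37, adjusted p = 2.98e-05) followed. Also higher were the basement membrane protein gene Nid1 (3.73), the imprinted noncoding RNA H19 (3.73), the epidermal growth factor receptor family ligand Nrg1 (3.61), osteopontin (Spp1, 3.50), cyclin A2 (Ccna2, 3.52), Spink1 (3.87), Fads3 (3.80), Pak6 (3.06) and Bicc1 (2.98). Within that limit the falls were led by the calmodulin kinase subunit gene Camk2b (-2.80 ± 0.36, adjusted p = 5.12e-04), the taurine synthesis gene Csad (-2.47), Cryl1 (-2.11) and Rnf187 (-1.96). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell too (-1.56 ± 0.35, adjusted p = 0.033). In all, 150 of 10681 genes were higher and 18 lower, with a median change over all genes of 0.07 as deposited and -0.05 after quantile normalization.

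Among the gene groups of the Sox9-heterozygous YAP group, cell cycle genes came first by count (9 of 25 rose, 13 adjusted over the list alone), with a median change of 1.13 (camera adjusted p = 2.68e-15, adjusted p = 0.144 with an estimated correlation). Among them were cyclin D1 (Ccnd1, 2.77), Cdc20 (2.67) and the topoisomerase gene Top2a (2.07). Of 21 cholangiocyte and progenitor markers 6 rose (10 adjusted over the list alone), among them Pkhd1 (1.96) beside Sox4, Spp1 and Bicc1 (camera adjusted p = 4.88e-09, adjusted p = 0.0138 with an estimated correlation). Of 19 YAP and TAZ target genes 3 rose (7 adjusted over the list alone), namely Ctgf, Cyr61 (2.03) and Crim1 (1.65), with a median of 0.93 (camera adjusted p = 4.02e-06, adjusted p = 0.17 with an estimated correlation). The Hippo pathway components had a median of 0.80, and the adaptor gene Ajuba alone of 23 rose (1.97, 10 adjusted over the list alone, camera adjusted p = 1.88e-04, adjusted p = 0.144 with an estimated correlation). The pericentral hepatocyte genes were lower as a list (median -0.63, camera adjusted p = 1.79e-07, adjusted p = 0.144 with an estimated correlation). By limma, 0 of 22 members passed over all genes and 2 fell adjusted over the list alone. The glutamate transporter gene Slc1a2 was at -1.97 ± 0.48, adjusted p = 0.0522. Endothelial cell markers moved with these groups: all 18 of 18 had positive changes, with a median of 1.48 (camera adjusted p = 3.44e-09, adjusted p = 0.17 with an estimated correlation). Lyve1 (2.57) and Flt4 (1.90) rose (11 members adjusted over the list alone). These 6 lists kept their camera call with any 1 library left out. Over the 6 comparisons, 62 of the 91 medians of called lists moved by over 1.5 times or across 0 with 1 library left out.

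A further 11 lists were called in the Sox9-heterozygous YAP group, but each lost the call without at least 1 library, with a highest adjusted p of 0.0664 to 0.92. The fetal liver and liver tumour markers were one of them (3 of 15 rose, 5 adjusted over the list alone, camera adjusted p = 0.0223, adjusted p = 0.17 with an estimated correlation), with Ly6d (1.91) beside Gpc3 and H19. The acute phase response list was higher (median 0.34, camera adjusted p = 0.0264, adjusted p = 0.603 with an estimated correlation), with the metalloreductase gene Steap4 (2.33) and the iron-binding lipocalin gene Lcn2 (2.27) rising. It was on the other side without library 2 of this group (adjusted p = 0.0743) and not called without library 1 of the wild type control (0.0866). Without library 1 of the wild type control and libraries 1 and 2 of this group, the fetal liver list had an adjusted p of 0.0866, 0.0645 and 0.0779. Actin cytoskeleton and integrin genes (3 of 26 rose, 4 adjusted over the list alone, camera adjusted p = 4.11e-04, adjusted p = 0.34 with an estimated correlation) included Anxa2 (2.73) and filamin A (Flna, 2.52). Their adjusted p was 0.131 without library 1 of this group. The bile acid list was lower (median -0.13, camera adjusted p = 0.0109, adjusted p = 0.17 with an estimated correlation), as were the periportal genes (median -0.37, camera adjusted p = 4.11e-04, adjusted p = 0.17 with an estimated correlation). The bile acid call ended after quantile normalization (adjusted p = 0.0749), without library 2 of the wild type control (0.196) and without library 1 of this group (0.0577), and the periportal call ended without library 1 of this group (0.0664). The 2 libraries of this group differed, and not in strength alone. Their correlation across genes, 0.953, was the lowest of any group. The median of the YAP and TAZ target genes was 1.42 above the GFP libraries in library 1 and 0.26 in library 2. Cell cycle genes went the same way (1.56 and 1.09). Library 2 was further from the GFP libraries for the pericentral genes (-0.93, against -0.49 in library 1). The same held for the acute phase list (1.23 against -0.09) and the chemokines and cytokines (0.67 against -0.04). With 1 library left out, Cyp7a1 ranged from -2.17 to -0.96, Cyr61 from 1.24 to 2.83, Cdc20 from 1.56 to 3.78, Steap4 from 1.07 to 3.59 and Lcn2 from 1.22 to 3.33, and each lost its call. Leaving out library 2 gave 291 calls in this comparison, and leaving out library 1 of the wild type control gave 92.

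The second comparison set YAP S127A with both Sox9 alleles deleted against the wild type control. Gpc3 rose by 7.77 ± 0.46, adjusted p = 2.0e-07, H19 by 6.55 ± 0.41, adjusted p = 2.0e-07 and Sox4 by 5.35 ± 0.37, adjusted p = 5.18e-07. The other large rises were Spink1 (5.93), Nid1 (5.47), Fads3 (5.42), the female-biased cytochrome P450 gene Cyp2b9 (5.37), Fgd3 (5.25), the metalloproteinase inhibitor gene Timp2 (4.92), Glis2 (4.82) and Ctgf (4.53). The largest falls were those of Tmub2 (-4.31 ± 0.27, adjusted p = 2.0e-07) and of the immediate early transcription factor gene Egr1 (-3.11 ± 0.29, adjusted p = 8.76e-06). They were followed by Camk2b (-3.10), the pericentral genes Slc1a2 (-3.05), Oat (-2.46) and Glul (-2.51), the oxysterol hydroxylase gene Cyp7b1 (-2.61), Ddit4 (-2.60), Nnmt (-2.25) and Fos (-2.19). In all, 709 genes were higher and 51 lower. The share of calls that were higher was 93.3% as deposited, 80.2% with library medians equalised and 78.4% after quantile normalization, where the median change over all genes was -0.08 in place of 0.21.

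In the Sox9-null YAP group, of the 25 cell cycle genes 17 rose (23 adjusted over the list alone), with a median of 2.12 (camera adjusted p = 1.03e-17, adjusted p = 0.0797 with an estimated correlation). The largest changes named were those of Ccna2 (4.25), Ccnd1 (3.94), Cdc20 (3.56) and Top2a (3.46). Of the YAP and TAZ target genes 9 rose (12 adjusted over the list alone), with a median of 1.54 (camera adjusted p = 3.37e-08, adjusted p = 0.0988 with an estimated correlation). Among them were the phosphatase gene Ptpn14 (2.44) and the angiomotin-like gene Amotl2 (2.09). Of 23 Hippo components 11 rose (12 adjusted over the list alone), including the YAP partner Tead4 (3.78), Ajuba (2.88) and Tead2 (2.41) (camera adjusted p = 1.61e-05, adjusted p = 0.0797 with an estimated correlation). Of the 21 cholangiocyte and progenitor markers 7 rose (10 adjusted over the list alone) and 1 fell (camera adjusted p = 1.20e-04, adjusted p = 0.0797 with an estimated correlation), with Bicc1 (4.43), Pkhd1 (3.23) and Slc5a1 (3.20) beside Sox4. Notch genes (2 of 9 rose, 5 adjusted over the list alone, camera adjusted p = 0.00363, adjusted p = 0.191 with an estimated correlation) included the ligand Jag1 (2.58) and its effector Hes1 (2.21). Extracellular matrix genes (5 of 20 rose, 7 adjusted over the list alone, camera adjusted p = 0.00116, adjusted p = 0.119 with an estimated correlation) included the laminins Lamb2 (4.27) and Lama5 (2.85).

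Lower lists in the Sox9-null YAP group were led by the pericentral genes (5 of 22 fell, 6 adjusted over the list alone, camera adjusted p = 2.24e-12, adjusted p = 0.0797 with an estimated correlation). The male-biased liver genes followed, with 0 of 11 positive, and a median of -1.82, where 1 fell (7 adjusted over the list alone), namely Cyp7b1 (camera adjusted p = 4.70e-10, adjusted p = 0.119 with an estimated correlation). That median was -0.54 without library 1 of this group and -2.97 without library 2. Of the 22 immediate early genes 3 fell (4 adjusted over the list alone), namely Egr1, Fos and Ier2 (-1.21), while Klf6 rose (1.78, camera adjusted p = 2.47e-04, adjusted p = 0.112 with an estimated correlation). The median of that list was -0.17, and it was 0.14 without library 2 of this group. The hepatocyte transcription factor and secreted protein list was called lower (camera adjusted p = 0.0215, adjusted p = 0.112 with an estimated correlation) with a median of 0.02, a mean of -0.06 and 0 members passing. That call ended after quantile normalization (adjusted p = 0.404) and without library 2 of this group (0.0706). The bile acid list was also called lower (camera adjusted p = 0.0429, adjusted p = 0.219 with an estimated correlation) although its median was 0.02 and its mean 0.0029, and fry put it on the other side (adjusted p = 0.769). The bile acid call ended after quantile normalization (0.511), without library 2 of the wild type control (0.338) and without library 2 of this group (0.546). Endothelial markers were again all positive, with a median of 2.26 (7 of 18 rose, 16 adjusted over the list alone, camera adjusted p = 4.70e-10, adjusted p = 0.119 with an estimated correlation). Lyve1 (2.99), Stab1 (2.69) and Kdr (2.46) were among those that rose. Of 21 lists called, 15 kept the call with any 1 library left out. With 1 library left out, Cyp2b9 ranged from 3.05 to 7.68, Cyp7b1 from -3.59 to -1.63, Oat from -3.40 to -1.52, Hes1 from 1.09 to 3.33 and Stab1 from 1.71 to 3.67, and each lost its call. The count of 760 genes became 354 and 470 without libraries 1 and 2 of the wild type control, 471 and 328 without libraries 1 and 2 of the Sox9-null YAP group, and 483 when only the YAP experiment was fitted.

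**Figure D2:**
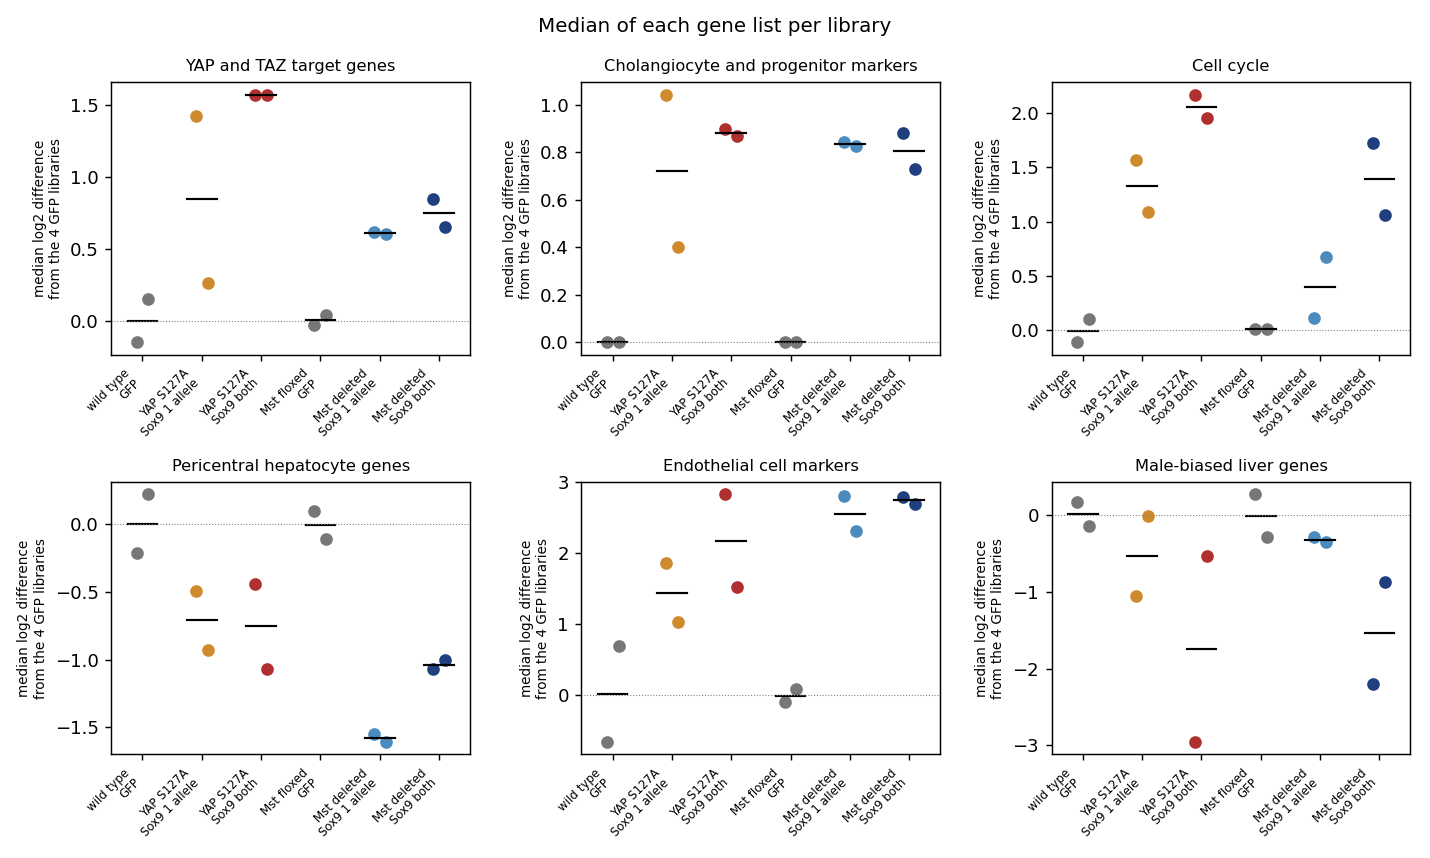
Median, over the members of 6 gene lists, of the log2 difference from the mean of the 4 GFP libraries, with 1 point per library and a bar at the mean of each group. The YAP and TAZ target genes stood at 1.42 and 0.26 in the 2 Sox9-heterozygous YAP libraries, the pericentral genes at -1.55 and -1.61 in the Sox9-heterozygous Mst libraries, and the male-biased genes at -2.96 and -0.53 in the Sox9-null YAP libraries.

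The third comparison, Sox9-null against Sox9-heterozygous hepatocytes under YAP S127A, asked what the second Sox9 allele contributed. Besides Sox9, the falls named were those of Tmub2 (-4.25 ± 0.27, adjusted p = 5.48e-07), Egr1 (-2.67 ± 0.29, adjusted p = 3.66e-04), Fos (-2.57 ± 0.45, adjusted p = 0.0274) and the elastase gene Cela1 (-1.74 ± 0.30, adjusted p = 0.0262). Among genes with a mean log2 of at least 4 in the higher group, the largest rises were those of Vamp2, a vesicle fusion protein gene (4.92 ± 0.53, adjusted p = 3.66e-04), and H19 (2.83 ± 0.41, adjusted p = 0.00709). Also higher were the fatty acid hydroxylase gene Cyp4a31 (2.73), the lipolysis inhibitor gene G0s2 (2.29), Rnf187 (2.13), Pcolce (2.02), the efflux transporter gene Abcb1a (1.96), Mgst3 (1.82), Crat (1.81), the macrophage growth factor gene Csf1 (1.77) and Tagln2 (1.5). In all, 12 genes were higher and 6 lower, with a median change over all genes of 0.15 as deposited and -0.02 after quantile normalization. YAP and TAZ target genes did not fall as a list with Sox9 loss: 17 of 19 had positive changes, with a median of 0.66 and 0 members passing limma (camera adjusted p = 0.00577, adjusted p = 0.288 with an estimated correlation). Cholangiocyte and progenitor markers had a median of 0.12 and were not called (test direction lower, adjusted p = 0.873), with Sox9 itself the 1 member that passed. Adjusted over the list alone, 5 were higher and 1 lower.

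With Sox9 loss under YAP S127A, all 22 cholesterol and fatty acid synthesis genes had positive changes (median 0.66, 3 passing adjusted over the list alone and 0 over all genes by limma, camera adjusted p = 4.56e-08, adjusted p = 0.146 with an estimated correlation). Among them were the lipase gene Pnpla3 at 1.60 ± 0.47 and malic enzyme Me1 at 1.26 ± 0.31. Cell cycle genes were higher as a list (median 0.86, 24 of 25 positive, camera adjusted p = 1.35e-07, adjusted p = 0.195 with an estimated correlation), with Top2a at 1.40 ± 0.36, 6 members passing adjusted over the list alone and 0 over all genes. Immediate early genes were lower relative to all genes (2 of 22 fell, 3 adjusted over the list alone, camera adjusted p = 3.95e-07, adjusted p = 0.139 with an estimated correlation). Their median was only -0.06, against 0.15 over all genes, and it was 0.09 without library 2 of the Sox9-null group. Female-biased genes were higher (median 2.10, 10 of 10 positive, 6 passing adjusted over the list alone and 0 over all genes by limma, camera adjusted p = 2.26e-06, adjusted p = 0.139 with an estimated correlation), with Hao2 at 2.95 ± 0.78. These 4 lists kept the camera call with any 1 library left out. Another 12 lists were called but ended or turned without at least 1 library. They included the fatty acid oxidation list (all 20 positive, median 0.60, 7 passing adjusted over the list alone, camera adjusted p = 5.07e-07, adjusted p = 0.139 with an estimated correlation, adjusted p = 0.111 without library 1 of the Sox9-null group), with the PPARA target Cyp4a14 at 5.01 ± 1.40. The male-biased genes (median -1.34, 0 of 11 positive, 1 passing adjusted over the list alone, camera adjusted p = 7.62e-11, adjusted p = 0.146 with an estimated correlation) had an adjusted p of 0.211 without the same library. The YAP and TAZ targets had 0.796 without library 2 of the Sox9-heterozygous group and 0.155 without library 1 of the Sox9-null group. Drug metabolism enzymes were called lower (camera adjusted p = 0.0416, adjusted p = 0.341 with an estimated correlation) with a median of 0.01 and a mean of 0.0027. The call turned in fry (adjusted p = 0.979) and without library 2 of the Sox9-null group (0.693), and ended after quantile normalization (0.714) and without library 1 of the Sox9-heterozygous group (0.377). The endothelial markers moved in the same direction as the YAP and TAZ targets, with 18 of 18 positive and a median of 0.71 (camera adjusted p = 0.00604, adjusted p = 0.472 with an estimated correlation). They had an adjusted p of 0.446 without library 2 of the Sox9-heterozygous group and turned without library 1 of the Sox9-null group (0.482). The 18 calls became 128 and 4 without libraries 1 and 2 of the Sox9-heterozygous group, 7 without either Sox9-null library and 9 in a fit of the YAP experiment alone.

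The fourth comparison set Mst1 and Mst2 deletion with 1 Sox9 allele deleted against the floxed control. Ctgf rose by 6.30 ± 0.35, adjusted p = 9.29e-08, Nid1 by 5.65 ± 0.42, adjusted p = 1.58e-06, Nrg1 by 5.29 ± 0.35, adjusted p = 5.79e-07 and Sox4 by 5.21 ± 0.37, adjusted p = 9.65e-07. The neurotrophin receptor gene Ntrk2 (4.77), the prostaglandin synthase gene Ptgds (4.69), Ly6d (4.27), the milk fat globule protein gene Mfge8 (4.23), H2-Q1 (4.27), Cib3 (4.22), Eng (4.20) and Bicc1 (4.19) rose as well. The falls were led by 3 pericentral genes, Slc1a2 (-6.05 ± 0.48, adjusted p = 2.51e-06), Oat (-5.32 ± 0.50, adjusted p = 1.25e-05) and Lhpp (-5.00 ± 0.50, adjusted p = 1.97e-05). Other falls were those of the ectonucleotidase gene Nt5e (-3.73), the replication factor gene Mcm10 (-3.03), the phosphatidate phosphatase gene Lpin1 (-3.0), Cyp2c68 (-2.69) and Ctsc (-2.39). In all, 369 genes were higher and 85 lower, with a median change over all genes of 0.08 as deposited and -0.05 after quantile normalization.

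Of 22 pericentral genes 10 fell (11 adjusted over the list alone) in the Sox9-heterozygous Mst group, including the R-spondin receptor gene Lgr5 (-2.70), with a median of -1.37 (camera adjusted p = 1.73e-15, adjusted p = 0.0497 with an estimated correlation). Cholangiocyte and progenitor markers included 8 of 21 that rose (8 adjusted over the list alone, camera adjusted p = 1.29e-08, adjusted p = 0.0158 with an estimated correlation), with Spp1 (4.17) and the keratin gene Krt23 (3.91) beside Sox4 and Bicc1. Of the YAP and TAZ target genes 4 rose (7 adjusted over the list alone) and 1 fell, with Ctgf, Cyr61 (2.75) and Crim1 (2.15) against Nt5e (median 0.78, camera adjusted p = 5.60e-04, adjusted p = 0.314 with an estimated correlation). Actin cytoskeleton and integrin genes (8 of 26 rose, 12 adjusted over the list alone, camera adjusted p = 9.14e-06, adjusted p = 0.314 with an estimated correlation) included the annexins Anxa5 (3.32) and Anxa2 (3.12). Of 22 cholesterol and fatty acid synthesis genes 2 rose (7 adjusted over the list alone), namely Elovl6 (1.57) and Mvd (1.31, camera adjusted p = 0.00288, adjusted p = 0.341 with an estimated correlation). The Notch list was higher (median 0.90, camera adjusted p = 0.0122, adjusted p = 0.314 with an estimated correlation) with the receptor gene Notch1 passing (1.72). Endothelial markers had 18 of 18 positive changes and a median of 2.66 (10 of 18 rose, 16 adjusted over the list alone, camera adjusted p = 3.73e-17, adjusted p = 0.179 with an estimated correlation). Those that rose included Eng, Stab2 (3.82) and Clec4g (3.78). Among the lists whose call ended without at least 1 library were the interferon response genes (median -0.22, camera adjusted p = 0.0212, adjusted p = 0.345 with an estimated correlation), where Irf7 fell (-1.41) and Ifit2 rose (2.66). The adjusted p of that list was 0.0571 without library 1 of this group. The cell cycle genes (6 of 25 rose, 7 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.462 with an estimated correlation) had an adjusted p of 0.0632 without library 2. The 454 calls became 221 and 194 without libraries 1 and 2 of the floxed control, and 189 without library 2 of the Sox9-heterozygous Mst group.

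The fifth comparison set Mst1 and Mst2 deletion with both Sox9 alleles deleted against the floxed control. Ctgf (6.80 ± 0.35, adjusted p = 3.0e-08), Nid1 (6.57 ± 0.42, adjusted p = 1.80e-07), Nrg1 (5.67), Gpc3 (5.18), Sox4 (5.18), Ly6d (5.04), Ptgds (4.93), Mfge8 (4.92), Bicc1 (4.81), Lrtm2 (4.54) and Fads3 (4.54) rose. Slc1a2 (-6.09 ± 0.48, adjusted p = 1.16e-06), Oat (-5.06), Tmub2 (-4.48 ± 0.27, adjusted p = 1.10e-07), Lhpp (-4.02), Nt5e (-3.73), the male-biased serpin gene Serpina1e (-3.51), glutamine synthetase (Glul, -3.05), Mcm10 (-3.09) and the glucocorticoid-induced gene Tsc22d3 (-2.70) fell. In all, 735 genes were higher and 94 lower. The share of calls that were higher was 88.7% as deposited, 73.9% with library medians equalised and 73.7% after quantile normalization, where the median change over all genes was -0.08 in place of 0.17.

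In the Sox9-null Mst group, of the 22 pericentral genes 8 fell (11 adjusted over the list alone), with a median of -1.16, and 1 rose (camera adjusted p = 1.31e-13, adjusted p = 0.0683 with an estimated correlation). Of 21 cholangiocyte and progenitor markers 8 rose (8 adjusted over the list alone) and Sox9 fell (camera adjusted p = 1.07e-05, adjusted p = 0.058 with an estimated correlation), with Spp1 at 4.41 and Krt23 at 4.09. Of the 25 cell cycle genes 12 rose (18 adjusted over the list alone), with camera adjusted p = 5.31e-10, adjusted p = 0.151 with an estimated correlation, such as Ccnd1 (4.21) and Cdc20 (3.54). Of 17 p53 target and apoptosis genes 5 rose (11 adjusted over the list alone), with camera adjusted p = 4.37e-04, adjusted p = 0.151 with an estimated correlation. These included the polo-like kinase gene Plk2 (3.13), Phlda3 (2.64) and the stress cytokine gene Gdf15 (2.22). Chemokine and cytokine genes (6 of 18 rose, 8 adjusted over the list alone, camera adjusted p = 0.00154, adjusted p = 0.157 with an estimated correlation) included the monocyte attractant Ccl2 (2.58) and Cxcl16 (2.59). The drug metabolism enzymes were lower as a list (median -0.29, camera adjusted p = 2.90e-04, adjusted p = 0.151 with an estimated correlation) with Cyp2c37 the 1 member that fell (-2.59). Of the 11 male-biased genes 5 fell (6 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 5.47e-06, adjusted p = 0.226 with an estimated correlation). Among them were the steroid dehydrogenase gene Hsd3b5 (-3.70) and Elovl3 (-2.96). The median was -0.85 without library 1 of this group and -2.18 without library 2, and Elovl3 lost its call with 1 library left out (highest adjusted p = 0.194). Endothelial markers stood at a median of 2.71 (12 of 18 rose, 16 adjusted over the list alone, camera adjusted p = 1.31e-13, adjusted p = 0.151 with an estimated correlation). The macrophage and Kupffer cell markers were also higher (3 of 14 rose, 5 adjusted over the list alone, camera adjusted p = 0.00431, adjusted p = 0.285 with an estimated correlation). Mpeg1 (2.48), Cd68 (2.05) and the CSF1 receptor gene Csf1r (1.91) passed. That call ended without library 1 of this group (adjusted p = 0.112). The TGF-beta list (4 of 20 rose, 6 adjusted over the list alone, camera adjusted p = 0.0438, adjusted p = 0.23 with an estimated correlation), which held the matrix-binding protein gene Ltbp4 (2.88) and Tgfb1 (2.0), was one of 5 lists of 18 whose call ended without at least 1 library. Its adjusted p was 0.194 without library 1 of the floxed control, 0.0553 and 0.0539 without libraries 1 and 2 of this group, and 0.0518 and 0.0517 without libraries 1 and 2 of the Sox9-null YAP group. The 829 calls became 383 and 447 without libraries 1 and 2 of the floxed control and 348 without library 1 of the Sox9-null Mst group.

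Between Sox9-null and Sox9-heterozygous hepatocytes after Mst deletion, the sixth comparison, 5 genes passed. Sox9 and Tmub2 (-4.38 ± 0.27, adjusted p = 3.41e-07) and the vesicle transport gene Sec22a (-2.33 ± 0.33, adjusted p = 0.0114) fell. Vamp2 (3.51 ± 0.53, adjusted p = 0.0155) and the noncoding transcript 2610507I01Rik (3.06 ± 0.45, adjusted p = 0.0137) rose. All 25 cell cycle genes had positive changes, with a median of 0.95 (camera adjusted p = 3.32e-13, adjusted p = 0.294 with an estimated correlation). Of them 4 passed adjusted over the list alone and 0 over all genes by limma. The replication gene Mcm5 stood at 1.65 ± 0.37 and Mki67 at 1.58 ± 0.47. None of 11 male-biased genes was positive (median -0.83, camera adjusted p = 1.18e-07, adjusted p = 0.502 with an estimated correlation), with Elovl3 at -2.06 ± 0.72 and Hsd3b5 at -1.78 ± 0.68. The cholesterol and fatty acid synthesis list was lower (median -0.20, camera adjusted p = 0.00129, adjusted p = 0.502 with an estimated correlation). The fetal liver and liver tumour markers were higher (15 of 15 positive, camera adjusted p = 0.0051, adjusted p = 0.294 with an estimated correlation). The YAP and TAZ targets were not called (median 0.18, adjusted p = 0.528), nor were the endothelial markers (median -0.01, adjusted p = 0.324) or the pericentral genes (median 0.28, adjusted p = 0.517). The median over all genes was 0.09 as deposited and -0.03 after quantile normalization. The 5 calls became 20 and 3 without libraries 1 and 2 of the Sox9-heterozygous Mst group and 2 in a fit of the Mst experiment alone. The cholesterol and fetal liver calls ended without library 1 of that group (adjusted p = 0.0715 and 0.108).

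Glycolysis genes and stellate cell and fibroblast markers were not called by camera in any of the 6 comparisons. Their medians were 0.18 and 0.97 in the Sox9-null Mst group (adjusted p = 0.912 and 0.231), where the pyruvate kinase gene Pkm (2.0) and the matrix gene Dcn (2.59) rose. Of the markers of T and NK cells, B cells and neutrophils 0 genes passed the filter on low values, and 1 erythroid marker did, so these 4 lists were not tested.

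The 2 ways of activating YAP were compared over the Sox9-heterozygous groups, which share no control libraries. The means of these controls had been made equal gene by gene. Independence of the 2 activation effects, behind the expected numbers, shared signs and correlations below, is therefore not assured. Unless the other libraries were moved alike, both effects are measured from 1 common control profile, which by itself makes them agree in part. The agreement that this alone would give was not computed. Of the genes higher in each, 93 were higher in both, where 5.18 would be expected of independent lists, and 2 were lower in both (0.143 expected). None was called in opposite directions. Of the 150 genes higher under YAP S127A 144 had a positive change after Mst deletion. Across the 10681 genes, which are not independent replicates, the fold changes correlated with r = 0.477 and rho = 0.312. For Sox9 loss, Vamp2 and 2610507I01Rik were higher, and Sox9 and Tmub2 lower, in both experiments, with 0.00225 and 0.00169 genes expected of independent lists. Sox9 was deleted by design in both, so its place among the shared genes was fixed in advance. All 4 genes lie on chromosome 11, which carried the floxed Sox9 allele in both experiments. Independence is therefore not assured here either. Across genes r was 0.229 and rho 0.181. The count shared for activation, 95 in all, came to 59 without library 1 of the wild type control. The 4 shared for Sox9 loss came to 2 without library 2 of the Sox9-heterozygous YAP group, library 2 of the Sox9-heterozygous Mst group or library 1 of the Sox9-null Mst group.

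**Figure D3:**
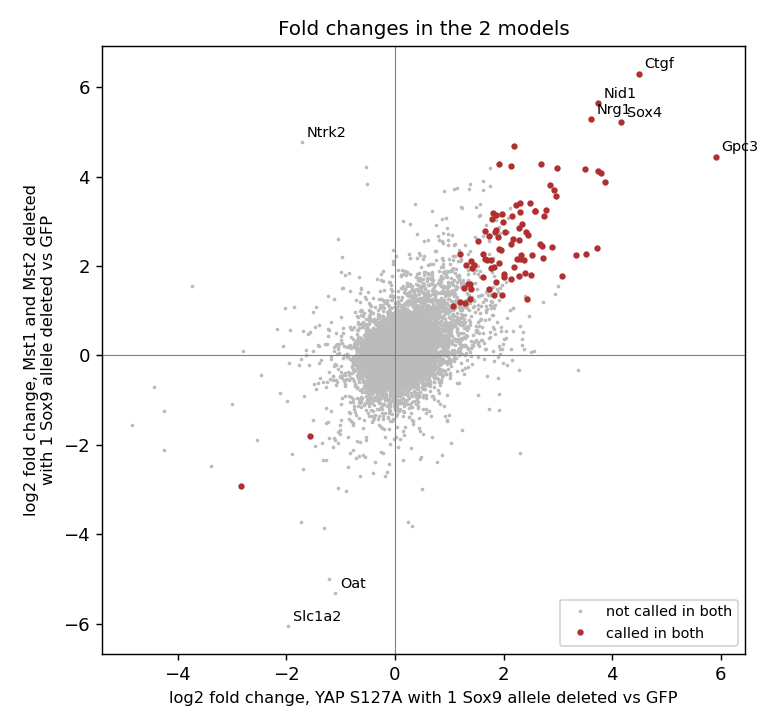
Log2 fold change of each of 10681 genes in the Sox9-heterozygous YAP group (horizontal axis) and the Sox9-heterozygous Mst group (vertical axis), each against its own control, with genes called in both in red. Ctgf lay at 4.49 and 6.30, Gpc3 at 5.91 and 4.45, and the correlation across genes was 0.477. The control means had been made equal gene by gene. Unless the other libraries were moved alike, both axes are measured from a common control profile, which by itself gives a correlation. The size of that correlation was not computed, so 0.477 cannot show whether the responses agree beyond it.

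The difference between the 2 activation effects passed for 21 genes. The control means had been made equal gene by gene, so these values are close to the difference between the 2 Sox9-heterozygous groups themselves. The SE is that of the difference of the 2 effects, so it also holds the spread of the control libraries. Leaving out a control library undoes the equality of the control means, which bears on the counts without control libraries below. Whether other differences between the experiments are removed depends on how the other libraries were moved, which the values do not show. Oat, Slc1a2, Lhpp, 1600002H07Rik and Tlr12 were lower, relative to control, after Mst deletion than under YAP S127A by 4.21 ± 0.71, 4.08 ± 0.67, 3.79 ± 0.70, 4.13 ± 0.73 and 4.49 ± 0.82. In the other direction, Ntrk2 (-6.49 ± 0.72, adjusted p = 0.0017), the lipoprotein lipase gene Lpl (-4.35), Tmem51 (-3.08), Smpd3 (-3.01) and Camk2b (-2.90) had the lower effect under YAP S127A. The count ranged from 0 (without library 2 of the Sox9-heterozygous YAP group) to 39 (without library 1 of the Sox9-heterozygous Mst group). It was 3 and 13 without libraries 1 and 2 of the wild type control, 4 and 5 without libraries 1 and 2 of the floxed control, and 1 without library 2 of the Sox9-heterozygous Mst group. For the difference between the Sox9 loss effects 0 genes passed limma, with 322 at unadjusted p under 0.05, and 18 passed without library 1 of the Sox9-heterozygous YAP group.

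Genes called for activation in one experiment were then followed under Sox9 loss in the other, so that no group mean was used both to choose and to test them, although the spread was pooled over all 12 libraries. The 369 genes raised by Mst deletion were higher with Sox9 loss under YAP S127A (median 0.54 against 0.15 for all genes, 314 positive, camera p = 9.08e-15, p = 0.0433 with an estimated correlation). Endothelial markers moved the same way in that comparison (all 18 positive, median 0.71). Leaving the 10 of them that were raised out of the 369 genes gave a median of 0.54 (1.25e-14 by camera), a test chosen only after the result was seen. Endothelial genes outside the marker list would stay in the set, so this test does not decide whether endothelial RNA bears on the result. The 85 genes lowered by Mst deletion were lower (median -0.15, 30 positive, p = 1.97e-11, p = 0.0108 with an estimated correlation). The 150 genes raised by YAP S127A were higher with Sox9 loss after Mst deletion (median 0.41 against 0.09, 123 positive, p = 5.80e-10, p = 0.0765 with an estimated correlation). The 18 genes lowered by YAP S127A were higher as a set, with a median of 0.38 (10 positive, p = 0.00638, p = 0.0293 with an estimated correlation). By camera, that last call ended without library 1 of the wild type control (0.566), library 2 of the Sox9-heterozygous YAP group (0.665) and library 1 (0.471) or 2 (0.481) of the Sox9-null YAP group. The direction turned when 10 was added on the linear scale (0.779 by camera) and with the deviations before rescaling (0.00211), a setting chosen only after the result was seen. Of the 18 genes, Rnf187 rose by 1.63 with Sox9 loss after Mst deletion. Vamp2 and 2610507I01Rik, at -4.25 and -4.44 in the Sox9-heterozygous YAP group against its control, rose by 3.51 and 3.06. These genes lie on chromosome 11 with Sox9, and the set was not tested without them.

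Over both experiments together, with the experiment as a term and 4 libraries against 4, Sox9 loss was called for 7 genes. Tmub2 (-4.32 ± 0.20, adjusted p = 4.63e-07), Sox9 (-3.64 ± 0.42, adjusted p = 0.0024) and the cytochrome b561 gene Cyb561 (-1.81 ± 0.21, adjusted p = 0.0024) fell. Vamp2 (4.21 ± 0.37, adjusted p = 3.08e-04) and Rnf187 (1.88 ± 0.22, adjusted p = 0.0024) rose. The other 2 in this comparison, which fell outside the rule for named genes and were singled out after their values were seen, were 2610507I01Rik (3.85 ± 0.36, adjusted p = 5.21e-04) and the endocytosis gene Ehd2 (1.73 ± 0.26, adjusted p = 0.0331). All of them except Ehd2, which is on chromosome 7, lie on chromosome 11 (GRCm38): Rnf187 at 58932288 to 58938916, 2610507I01Rik at 59199836 to 59202385, Vamp2 at 69088490 to 69092384, Tmub2 at 102284931 to 102289237, Cyb561 at 105933702 to 105953336 and Sox9 at 112782224 to 112787760. Vamp2 stood at -0.87 ± 0.09 in the Sox9-heterozygous YAP group against 3.38 ± 0.72 in its control and 4.04 ± 0.68 in the Sox9-null group. Tmub2 stood at 4.92 ± 0.29, 4.98 ± 0.00 and 0.68 ± 0.00.

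**Figure D4:**
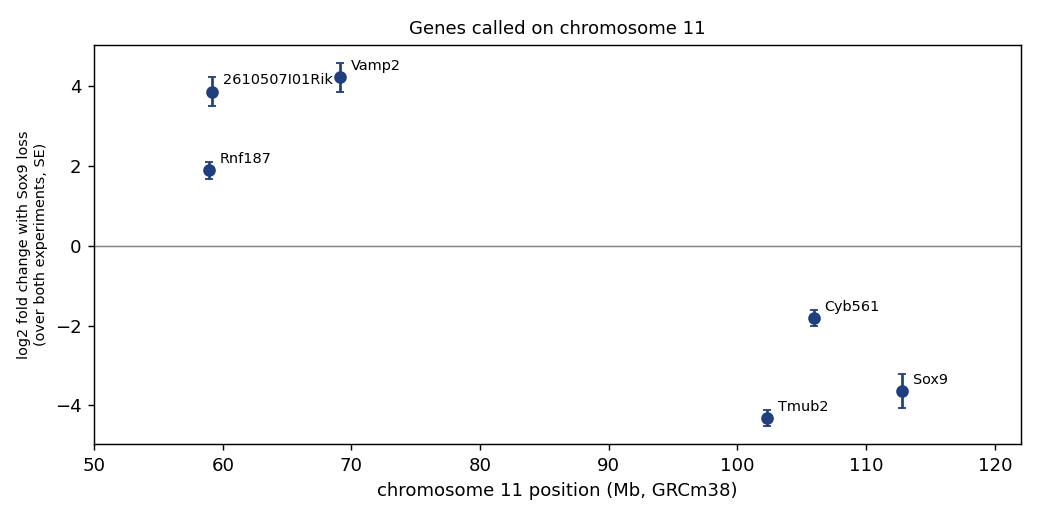
Position on chromosome 11 (horizontal axis, Mb, GRCm38) and log2 fold change with Sox9 loss over both experiments (vertical axis, bars are the SE) of the 6 called genes on that chromosome. Tmub2, Cyb561 and Sox9 were lower (-4.32, -1.81 and -3.64), and Rnf187, 2610507I01Rik and Vamp2 were higher.

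The wild type and floxed controls were compared as well. Their means had been made equal gene by gene before deposition, so the outcome (0 genes by limma, 0 at unadjusted p under 0.05) was fixed by that step and says nothing about the animals.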

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

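The tests of endothelial RNA, of scale, of sex, of single libraries and of chromosome 11 were chosen only after the result was seen, while the split test was set beforehand, except for the count of splits that keep groups together.

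A test of the difference between the activation effects of the 2 experiments passed for 21 genes. Since the control means had been made equal gene by gene, it nearly compares the 2 Sox9-heterozygous groups directly, across experiments. The YAP S127A effect minus the Mst deletion effect was 4.49 for Tlr12, 4.21 for Oat, 4.13 for 1600002H07Rik, 4.08 for Slc1a2 and 3.79 for Lhpp. It was -6.49 for Ntrk2, -4.35 for Lpl, -3.08 for Tmem51, -3.01 for Smpd3 and -2.90 for Camk2b. Time after injection, 3 weeks and 4 weeks, went with the experiment, and the count fell to 0 without library 2 of the Sox9-heterozygous YAP group.

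All 18 endothelial markers had positive changes in each of the 4 comparisons with a control (medians 1.48, 2.26, 2.66 and 2.71), and 0 of them are in another list. A shift of the scale of whole libraries was argued against, since the largest adjusted p of the list after quantile normalization was 3.40e-09. Endothelial cell RNA in varying amount stays open and may account for the pattern, since all 18 markers were also higher in library 2 than in library 1 of the wild type control, where no genotype differed (median 1.35, against 0.01 over all genes), and 14 and 16 were higher in library 1 of the Sox9-heterozygous and Sox9-null YAP groups. The markers did not move together in the floxed control and the Sox9-heterozygous and Sox9-null Mst groups (11, 10 and 8 higher in library 2). The means of the first and second libraries of the Mst experiment had been made equal gene by gene, which could have removed such a movement. These last counts therefore decide nothing. The gate on fluorescence, set by a virus with a hepatocyte promoter, would remove endothelial cells that do not fluoresce, while that against Epcam and CD45 would not, and Stab1, the marker highest in the wild type control (3.05), had a mean of 5.75 in the Sox9-null YAP group and 6.42 in the Sox9-heterozygous Mst group. Which fluorescent protein each group was sorted on is not given here, so a gate that differed between control and activated groups was not tested. Induction of the endothelial markers in hepatocytes by activated YAP was not tested and stays open too.

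None of the 11 male-biased liver genes was positive with Sox9 loss in either experiment (medians -1.34 and -0.83). Female mice in the Sox9-null groups were argued against by Ddx3y, which was at least 4.62 in all 4 of those libraries. Under YAP S127A the pattern may rest on library 1 of the Sox9-null group, without which the adjusted p was 0.211 and the median -0.12 (SD over members 0.48, and 0.47 with it), with 5 of 11 positive. After Mst deletion, without library 1 of the Sox9-null group, the adjusted p was 0.0449 and the median -0.46, so a single library and a change of the whole group cannot be told apart with 2 libraries. An effect of Sox9 itself was not tested apart from these and stays open.

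Of the 6 genes called for Sox9 loss over both experiments besides Sox9, 5 lie on chromosome 11 with it, against 853 of 10435 tested genes with a position (8.17%, Fisher exact p = 2.02e-05). A linked variant that lowers the Tmub2 signal in proportion to its copies was argued against, since Tmub2 with 1 floxed allele differed from the controls by -0.06 and -0.0986 (SE 0.27). Vamp2, 2610507I01Rik and Rnf187 stood below the control with 1 floxed allele (-4.25, -4.44 and -1.96 under YAP S127A, -1.25, -0.71 and -0.17 after Mst deletion) and above it with 2 (0.67, 0.21 and 0.18, then 2.26, 2.35 and 1.46), which goes against a signal that follows the number of copies one way. The distance outside the range from 0 to 2 copies was 1.96 for Rnf187 under YAP S127A and 0.17 after Mst deletion. In the same order it was 4.25 and 1.25 for Vamp2, 4.44 and 0.71 for 2610507I01Rik, and 0.53 and 1.935 for Cyb561. The smallest of these, 0.17, belongs to Rnf187 alone. Activation went with the floxed alleles, so for these 4 genes such a signal and an effect of activation cannot be told apart. A stretch of chromosome 11 carried along with the floxed allele stays open for the grouping, for Tmub2 only if 1 copy keeps the full signal, no genotype was measured, and an effect of Sox9 on its neighbours was not tested.

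Of the 34 splits of the 8 libraries that could be fitted, 1, the real one, gave as many as 7 genes, Sox9 among them, and the highest of the others gave 0. The labels do not say that the 2 libraries of a group came from separate mice, and the splits that keep each group together, 2 with the real one, were too few for a share under 0.05.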

How the results depend on the processing

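The comparison counts below are in the order Sox9-heterozygous YAP, Sox9-null YAP, Sox9 loss under YAP S127A, Sox9-heterozygous Mst, Sox9-null Mst and Sox9 loss after Mst deletion (168, 760, 18, 454, 829 and 5 as reported). Tests on deviations before rescaling and with the library number of the Mst experiment, the estimated correlation and the sets without endothelial markers in the Sox9 dependence, and leaving out libraries in the agreement were chosen only after the result was seen. The deviations before rescaling gave 1232, 2955, 499, 2115, 2795 and 205, with 635 and 74 for the differences of activation and of Sox9 loss, 260 for Sox9 loss over both experiments and 545 and 50 genes shared between experiments. Stk4 in the Sox9-null Mst group (-0.56) and Yap1 in the Sox9-heterozygous YAP group (0.91) then passed. With the library number of the Mst experiment as well, the values were 844, 2335, 250, 1574, 2259 and 35, then 311, 33, 126, 412 and 15, and Yap1 (0.91) passed. The smaller spread by construction gives more calls. That library number alone moved none of the counts by over 1.5 times. With no filter, more genes were tested and the counts were 72, 369, 5, 189, 416 and 2, with 3 for the difference of activation, 1 over both experiments, 39 and 1 shared, and Sox9 under YAP S127A (-2.40) not called. A stricter filter gave 17 over both experiments, and the mean of both contrasts 14. Fits within an experiment gave 483 (Sox9-null YAP), 9 and 2 (Sox9 loss). Equal medians gave 484 and quantile normalization 449 in the Sox9-null YAP group. With no trend, Sox9 loss under YAP S127A gave 6 with Sox9 (-2.40) not called, the difference of activation 3, and 62 and 2 were shared. With 10 added, the values were 92 (Sox9-heterozygous YAP), 32 (Sox9 loss under YAP S127A), 1 (difference of activation), and 52 and 2 shared. With the replicate block the difference of Sox9 loss gave 3, and the 6 counts were 177, 720, 20, 438, 802 and 5. The test of the 18 genes lowered by YAP S127A turned with 10 added (p = 0.779), with deviations before rescaling (0.00211) and with both changes (0.00278), where the genes called also differ in number, and the genes raised by YAP S127A had p = 0.0765 with an estimated correlation. There were 91 list calls, against 3 with an estimated correlation and 46 with fry, 6 of which were not among the 91, with the bile acid list in the Sox9-null YAP group (0.769) and drug metabolism under Sox9 loss (0.979) reversed. Where no construction is named, the cause was not tested. Among the values of named genes, 145 lost their call with no filter, 78 with no trend, 56 in fits within an experiment, 44 after quantile normalization, 42 with 10 added and 33 with equal medians, and none reversed under the settings run. An analysis of whole reads by limma-voom was set beforehand and was not run, because whole reads could not be recovered from the values.

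Of 332 calls of named genes, 155 ended without at least 1 library and 29 changes moved by over 1.5 times. Of the medians of the 91 called lists, 62 moved by over 1.5 times or across 0. Leaving out 1 library, the 6 counts ranged from 92 to 291, 328 to 1003, 4 to 128, 189 to 524, 348 to 981 and 3 to 20. The differences ranged from 0 to 39 (activation) and 0 to 18 (Sox9 loss), Sox9 loss over both experiments from 6 to 10, the genes shared from 59 to 123 and 2 to 5, the list calls from 79 to 99, and the controls stayed at 0. Sox9 ranged from -2.83 to -1.96 under YAP S127A and from -5.12 to -4.65 after Mst deletion, Yap1 from 0.75 to 1.08 and 0.91 to 1.47 in the YAP groups, Stk4 from -0.60 to -0.12 and -0.76 to -0.37, and Stk3 from 0.09 to 0.36 and 0.07 to 0.54 in the Mst groups. The Sox9 dependence p ranged from 4.62e-20 to 1.36e-07 and 4.76e-17 to 8.74e-05 (raised and lowered by Mst deletion), and from 1.12e-15 to 0.0041 and 1.21e-04 to 0.665 (by YAP S127A). Without library 2 of the Sox9-heterozygous YAP group the acute phase list reversed in that group (0.0743, over all libraries left out 1.99e-13 to 0.0866) and under Sox9 loss (0.0314, highest of 3.50e-17 to 0.0314). Under Sox9 loss the endothelial list reversed without library 1 (0.482, over 7.54e-09 to 0.482) and drug metabolism without library 2 (0.693, over 3.76e-04 to 0.693) of the Sox9-null YAP group. The read depth behind the values is unknown, so counting error could not be set apart from the spread between libraries, and with 2 libraries per group 22.4% of simulated changes of log2 1 were called.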

Other observations

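The fatty acid oxidation and PPARA target list, with a median of 0.60 with Sox9 loss under YAP S127A, had a median of -0.10 with Sox9 loss after Mst deletion. The difference between the experiments was not tested for this list.

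In the Mst experiment, the differences between the first and second library, summed over its 3 groups before the rescaling, were within 0.13 of 0 for 10571 kept genes. The sum was 0.99 in size for Sox9, 0.99 for Sstr2 and 0.31 for Cldn4, and the cause was not tested.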
